A study of Chlamydomonas reinhardtii with 16 samples.

How the data were processed

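RNA sequencing measured transcript levels in 16 libraries of the green alga Chlamydomonas reinhardtii. Per the labels' protocols, the 4A+ wild type and the heme oxygenase mutant hmox1 were grown in the dark on acetate medium with 0.5% methanol, with or without 0.1 mM biliverdin IXα (BV), a linear tetrapyrrole that heme oxygenase makes from heme. Cells were taken before and after 30 min of white light at 150 µmol photons m-2 s-1. The 2 strains, 2 treatments and 2 light conditions give 8 groups of 2 libraries, each taken from the sample labels. The labels do not say that the 2 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

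The deposited table holds 17301 genes and 16 columns of RPKM, reads scaled to gene length and to the total reads of the library. Its header does not name the unit. The unit was taken from the values, which are whole multiples of the worth of 1 read that depends on the gene and on the library. Per the submitters' processing notes, Bowtie was used, and its version is not given in the sources used here. Per the labels' protocols, reads were single-end and 100 nt long on a HiSeq instrument. The genome build, the annotation, the read counter, its use of strand and its treatment of reads with several matches are not given in the sources used here either, so no coordinates are printed. Genes that overlap or that have close copies can share reads.

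Depth was recovered from the RPKM steps. For each gene, the smallest whole length was sought that gives a whole number of reads in each library, within a tolerance of 0.1 reads. This worked for 16852 of the 16852 genes above 0 in any library. The largest distance from a whole read was 0.083, and 99.87% of the values above 0 lay within 0.01 reads. The recovered reads made up at least 99.999% of each library's inferred total. On simulated values of 16874 genes, 99.92% had their reads returned in each library. Reads and lengths are recovered only up to a common factor, which matters for genes seen in few libraries. Libraries held 10213599 to 43414933 reads in genes. At the shallowest depth, 3 reads of a 2-kb gene correspond to 0.147 RPKM, and at the deepest to 0.0346 RPKM. Read floors and intervals cover counting error only. The median recovered length was 2244 nt, and 303 genes had a recovered length under 200 nt, for which few reads give a high RPKM.

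The test was limma (version 3.58.1, in R 4.3.3) on log2(RPKM + 1), on the authors' scaling, with 1 mean per group over all 16 libraries, 8 residual degrees of freedom, a mean trend and robust moderation. Genes at 1 RPKM or more in at least 2 libraries were tested, 13972 in all. p-values were adjusted by Benjamini-Hochberg within each of 17 comparisons, and genes at adjusted p under 0.05 were called. There were 12 comparisons of 2 groups and 5 comparisons of effects. Log2 differences are on the log2(RPKM + 1) scale, which understates the change of low genes. The model was tested on simulated reads for the BV effect in wild type in the dark, over 13215 genes. It called 46% of the tested genes changed 1.5-fold and 89% of those changed 2-fold, and 5 genes among those left unchanged. Each gene had the same simulated spread in all groups, and counting error was added to a spread that already held it. The result therefore does not carry over to comparisons with light-treated wild type with BV, whose libraries differed most. The choices for the test, the comparisons and most alternatives were fixed before the data were examined.

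Identifiers were matched to the locus tags of the RefSeq assembly Chlamydomonas_reinhardtii_v5.5. Of the 17301 identifiers, 12666 (73.2%) matched. Among the 17742 RefSeq genes, 0 have a symbol other than the locus tag, and the deposited table does not pair identifiers with names, so genes are given by identifier and the mutated gene's own transcript was not identified here. The 29 gene lists fixed beforehand by symbol had too few members found (0 lists with 5 or more), so list tests were not run. The rule fixed beforehand named the 8 genes with the largest rise and the 8 with the largest fall in 4 main comparisons, and 3 each in the others. It took called genes whose libraries did not overlap between the groups compared, with at least 5 RPKM in the higher group and a gene name. As none had a name, this rule names no gene. In its place 2 identifiers per direction are printed in each comparison by the other criteria. After the values were seen, at least 20 reads in each library of the higher group were also required. This left out Cre05.g232400 and Cre35.g784050 (1 and 5 nt) for the strain in the dark and for the mutant with BV in the dark, Cre15.g642800 (58 nt) for the strain in the light, and Cre10.g429950 (86 nt) for BV in dark hmox1. The alternatives were recomputed for the printed identifiers only, a restriction made after a first run in which Cre10.g429950 changed direction with thinned libraries.

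After the data were seen, 2 sets of light-responsive genes were defined from the mean light effect over the 4 conditions (adjusted p under 0.05 and 2-fold or more). This mean weights the conditions equally, but light effects were widest in wild type without BV, which therefore had most influence on the choice. As a test, genes were also chosen on the libraries of the other strain alone. The alternatives fixed beforehand were a replicate block, TMM and quantile scaling, no mean trend, no low-value filter, a minimum of 10 RPKM, a pseudocount of 0.1, a 2-fold minimum, adjusted p under 0.01 for shared calls, only the groups compared, and each library left out. Added after seeing the data were voom on the recovered reads, libraries thinned to the shallowest depth, genes of 200 nt or more, and leaving out both libraries of light-treated wild type with BV. TMM factors were computed from the recovered reads by an own script, tested on simulated reads. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 served for recovery and plots.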

Results

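Transcript levels were measured by RNA sequencing in Chlamydomonas reinhardtii, a green alga that can grow in the dark on acetate. Wild type (strain 4A+) and hmox1, a mutant of heme oxygenase, were compared in the dark and after 30 min of light, each with and without 0.1 mM biliverdin IXα (BV), the product of heme oxygenase. The study concerned signalling by such bilins during greening. The transcript of the mutated gene was not identified here, since the identifiers could not be paired with gene names. Each of the 8 groups had 2 libraries, of 10213599 to 43414933 reads in genes. The shallowest library was wild type in the light without BV, replicate 2, and the deepest was hmox1 in the light without BV, replicate 2.

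The light condition separated the libraries most. The first principal component of log2(RPKM + 1) held 74.5% of the variance and parted dark from light libraries, and the second held 13.2% and parted the strains. On the first component the light libraries lay at 86.7 and 90.1 for wild type without BV, 58.3 and 56.5 for wild type with BV, 56.6 and 54.7 for hmox1 without BV, and 21.6 and 22.7 for hmox1 with BV. The dark libraries lay between -59.7 and -53.5. Pearson correlations between the 2 libraries of a group were 0.9941 to 0.9972 over the tested genes. The 2 libraries of wild type in the light with BV differed most, with a chi-square of 40.4 per gene against 3.51 to 7.54 in the other groups, and their RPKM summed to 968920 and 840589.

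**Figure D1:**
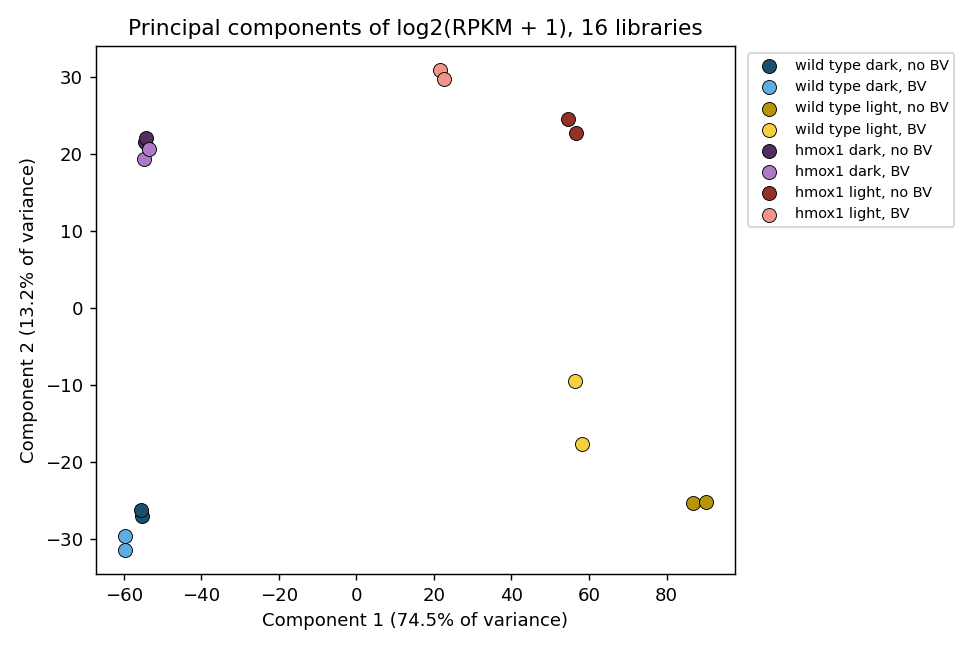
Principal components of log2(RPKM + 1) for the 16 libraries, with component 1 (74.5% of the variance) on the x axis, component 2 (13.2%) on the y axis, and 1 point per library coloured by group. The dark libraries lie at -59.7 to -53.5 on component 1 and the light libraries at 21.6 to 90.1.

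In the dark without BV, hmox1 differed from wild type in 4893 of 13972 genes. Only these strains were compared, so effects of the mutated gene cannot be told from other differences between them. Cre07.g339300 stood at 16.7 ± 0.635 RPKM in hmox1 and 0.0556 ± 0.0380 RPKM in wild type (SD, n = 2 each), a log2 difference of 4.07 ± 0.10 (SE, limma adjusted p = 5.3e-14). Cre17.g718134 rose from 2.32 ± 0.0199 to 41.9 ± 1.08 RPKM (log2 difference 3.69 ± 0.15, limma adjusted p = 1.1e-10). Cre03.g204200 had 524 reads in the wild-type libraries and 0 in the hmox1 libraries, which makes its rate at least 222.5-fold lower in hmox1 with a floor of 3 reads over the group, with a lower 95% Poisson limit of 180.3. Cre37.g784950 had 96 reads against 2, a rate 61.1-fold lower with a 95% Poisson interval of 16.5 to 512. By limma on the authors' scaling 3707 genes were higher and 1186 lower in hmox1, and 327 and 155 of these by 2-fold or more. The median gene was shifted by 0.12 in log2, and the share of higher genes among those called fell from 75.8% to 51.4% with TMM and 51.3% with quantile scaling. Both rescalings bring the median gene near 0, which by itself evens out higher and lower calls, so here and in the other comparisons they do not tell whether an excess of one direction is real. Larger fitted falls belonged to Cre05.g232400 and Cre35.g784050, of 1 and 5 nt recovered length, with 2 and 6 reads in wild type and 0 in hmox1.

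After 30 min of light without BV, the strains differed in 8557 genes. Cre02.g137700 was at 133.5 ± 2.98 RPKM in hmox1 and 0.641 ± 0.255 in wild type (SD, n = 2), a log2 difference of 6.36 ± 0.12 (SE, limma adjusted p = 2.1e-15). Cre11.g474600 was at 35.4 ± 1.82 against 0.265 ± 0.0298 RPKM (log2 difference 4.84 ± 0.08, limma adjusted p = 6.4e-16). Cre03.g204200 and Cre37.g784950 were again lower in hmox1, with 762 against 2 and 87 against 2 reads. Their rates were 695.5-fold (95% Poisson interval 192 to 5754) and 79.4-fold (21.3 to 666) lower. Limma called 7479 genes higher and 1078 lower, of which 692 and 61 changed 2-fold or more. The median shift was 0.29 in log2, and the share of higher genes was 87.4%, but 48.1% with TMM and 49.5% with quantile scaling.

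BV changed 764 genes in dark-grown wild type and 45 in dark-grown hmox1. In wild type Cre03.g163950 rose from 0.556 ± 0.0572 to 25.5 ± 1.23 RPKM (SD, n = 2; log2 difference 4.09 ± 0.10, limma adjusted p = 3.6e-13). Cre01.g045200 rose from 2.27 ± 0.620 to 52.2 ± 1.23 RPKM (log2 difference 4.04 ± 0.19, limma adjusted p = 1.1e-08). In hmox1 Cre01.g045200 rose from 2.57 ± 0.141 to 12.9 ± 2.01 RPKM (log2 difference 1.96 ± 0.19, limma adjusted p = 2.1e-04), and Cre07.g346900 from 3.76 ± 0.0394 to 9.99 ± 0.571 RPKM. The falls were smaller. Cre18.g748800 fell by 1.42 and Cre18.g748750 by 1.06 on the log2 scale in wild type (limma adjusted p = 0.021 and 0.028), and both calls were lost without replicate 1 of the untreated libraries or without either BV library, and with only the groups compared. With thinned libraries the call of Cre18.g748800 was lost as well. Cre02.g102050 fell by 0.83 and Cre14.g613800 by 0.82 in hmox1 (limma adjusted p = 8.8e-04 and 0.013). The call of Cre14.g613800 was lost without BV replicate 1, without either untreated library, with a pseudocount of 0.1 and with only the groups compared. Limma called 523 genes higher and 241 lower in wild type, and 27 and 18 in hmox1. In wild type the lower genes numbered 240 with TMM, 410 with quantile scaling and 98 without the mean trend, and in hmox1 9 with TMM and 16 with quantile scaling. The BV effects of the strains share no library, but calls in both rest on the same spread per gene, pooled over all groups. This favours shared calls, whatever their direction, beyond independent lists. Of the 27 genes that rose in hmox1, 25 also rose in wild type, against 1.0 for independent lists, and 0 fell. That overlap was 16 without either untreated hmox1 library.

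The dark BV response itself differed between the strains in 131 genes, 9 with a more positive and 122 with a more negative change in hmox1 (4 and 104 with TMM, 19 and 139 with quantile scaling). Cre03.g163950 reached 2.57 ± 0.154 RPKM in hmox1 with BV, and its response was smaller than that of wild type by a log2 difference of -2.76 ± 0.15 (SE, limma adjusted p = 3.7e-08). Cre13.g603550 rose from 7.73 ± 0.707 to 57.3 ± 6.48 RPKM with BV in wild type but stood at 93.8 ± 5.20 without and 94.8 ± 2.22 RPKM with BV in hmox1 (log2 difference of responses -2.72 ± 0.39, limma adjusted p = 8.7e-03). This call was lost without wild-type BV replicate 1 and with a pseudocount of 0.1. Cre16.g679018 and Cre12.g537225 had more positive changes in hmox1 by 0.96 and 0.71 (limma adjusted p = 0.044 and 0.025), but these calls were not stable. Both were lost with TMM, voom and thinned libraries, and without wild-type BV replicate 2, hmox1 BV replicate 1 or untreated hmox1 replicate 1. That of Cre16.g679018 was also lost without wild-type BV replicate 1, untreated wild-type replicate 2 or hmox1 BV replicate 2, and that of Cre12.g537225 without untreated wild-type replicate 1 or untreated hmox1 replicate 2. Leaving out a library leaves 1 in its group, which widens the standard error and by itself tends to lower a count. The counts that follow therefore do not show that a result rests on a particular library. The wild-type count was 248 or 327 without replicate 1 or 2 with BV and 307 or 467 without replicate 1 or 2 of the untreated libraries. The hmox1 count was 23 or 29 without replicate 1 or 2 with BV and 23 or 21 without replicate 1 or 2 of the untreated libraries. The count of differing genes was 75 or 71 without wild-type BV replicate 1 or 2, 83 without untreated wild-type replicate 1, 87 or 80 without hmox1 BV replicate 1 or 2, and 85 without untreated hmox1 replicate 1.

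In the light, BV lowered the level of several highly expressed genes. Cre01.g016600 stood at 924 ± 107 RPKM without and 18.6 ± 4.40 with BV in wild type, and at 544 ± 38.6 and 12.8 ± 0.378 in hmox1 (SD, n = 2; log2 differences -5.58 ± 0.47 and -5.31 ± 0.47, limma adjusted p = 1.7e-05 and 3.7e-05). Cre08.g367400 fell from 121.4 ± 0.915 to 1.54 ± 0.443 RPKM in wild type (log2 difference -5.60 ± 0.13, limma adjusted p = 2.2e-14). In hmox1 Cre02.g137700 fell from 133.5 ± 2.98 to 0.775 ± 0.188 RPKM (log2 difference -6.25 ± 0.12, limma adjusted p = 3.2e-15). Other genes rose. Cre07.g346950 went from 0.702 ± 0.00157 to 55.1 ± 0.686 RPKM in wild type and from 2.97 ± 0.137 to 69.45 ± 7.499 in hmox1. Cre17.g700950 rose from 8.43 ± 0.417 to 387.9 ± 43.3 RPKM in wild type (log2 difference 5.36 ± 0.09, limma adjusted p = 5.6e-16), and Cre07.g346900 from 0.653 ± 0.0344 to 20.9 ± 1.95 RPKM in hmox1.

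Limma called 4562 genes higher and 1814 lower with BV in light-treated wild type, and 3675 and 1563 in hmox1. With a median shift of 0.13 in log2 in each strain, the share of higher genes was 71.5% in wild type (3431 higher and 3426 lower with TMM, 53.9% with quantile scaling) and 70.2% in hmox1 (36.9% and 51.2%). The 2 responses share no library, but their calls again rest on the same pooled spread per gene. Over the tested genes, which are not independent replicates, they correlated with r = 0.71, with 2462 genes higher in both against 1199.9 for independent lists and 1106 lower in both against 202.9. The 2 light libraries of wild type with BV differed most from each other. Here and below, leaving out 1 of them also takes their spread out of the pooled estimate. Counts without 1 of them therefore do not show how far a result rests on them. Their median SD over genes was 0.120 in log2, against 0.053 to 0.076 in the other groups. The spread pooled over all groups is thus too small for comparisons with this group, here and below, and their p-values tend to be too low. With only the groups compared, fewer residual degrees of freedom remain. The count then went from 6376 to 4760 in wild type and from 5238 to 6398 in hmox1. In hmox1 it fell from 5238 to 3194 without replicate 1 of the untreated light libraries.

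The light-stage BV response differed between strains in 1196 genes, 342 more positive and 854 more negative in hmox1 (544 and 1236 with TMM, 420 and 699 with quantile scaling). Cre02.g137700 and Cre11.g474600 had the most negative differences among genes that met the rule for printing, -7.33 ± 0.17 and -4.86 ± 0.12 (SE, limma adjusted p = 7.3e-14 for each). Cre11.g474600 was at 35.4 ± 1.82 RPKM in hmox1 in the light without BV and at most 0.265 RPKM on average in the other 7 groups. Cre08.g367400 and Cre08.g367500 were lowered less in hmox1, by 1.94 ± 0.18 and 1.72 ± 0.17 (limma adjusted p = 3.8e-06 and 5.4e-06). Both calls were lost with a pseudocount of 0.1, and reads shared between these genes with neighbouring identifiers cannot be told from the table. The count was 2111 without replicate 2 of light-treated wild type with BV and 1248 without replicate 1. It was 754 without replicate 2 of light-treated wild type, 783 or 700 without hmox1 light BV replicate 1 or 2, and 601 or 735 without hmox1 light replicate 1 or 2.

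**Figure D2:**
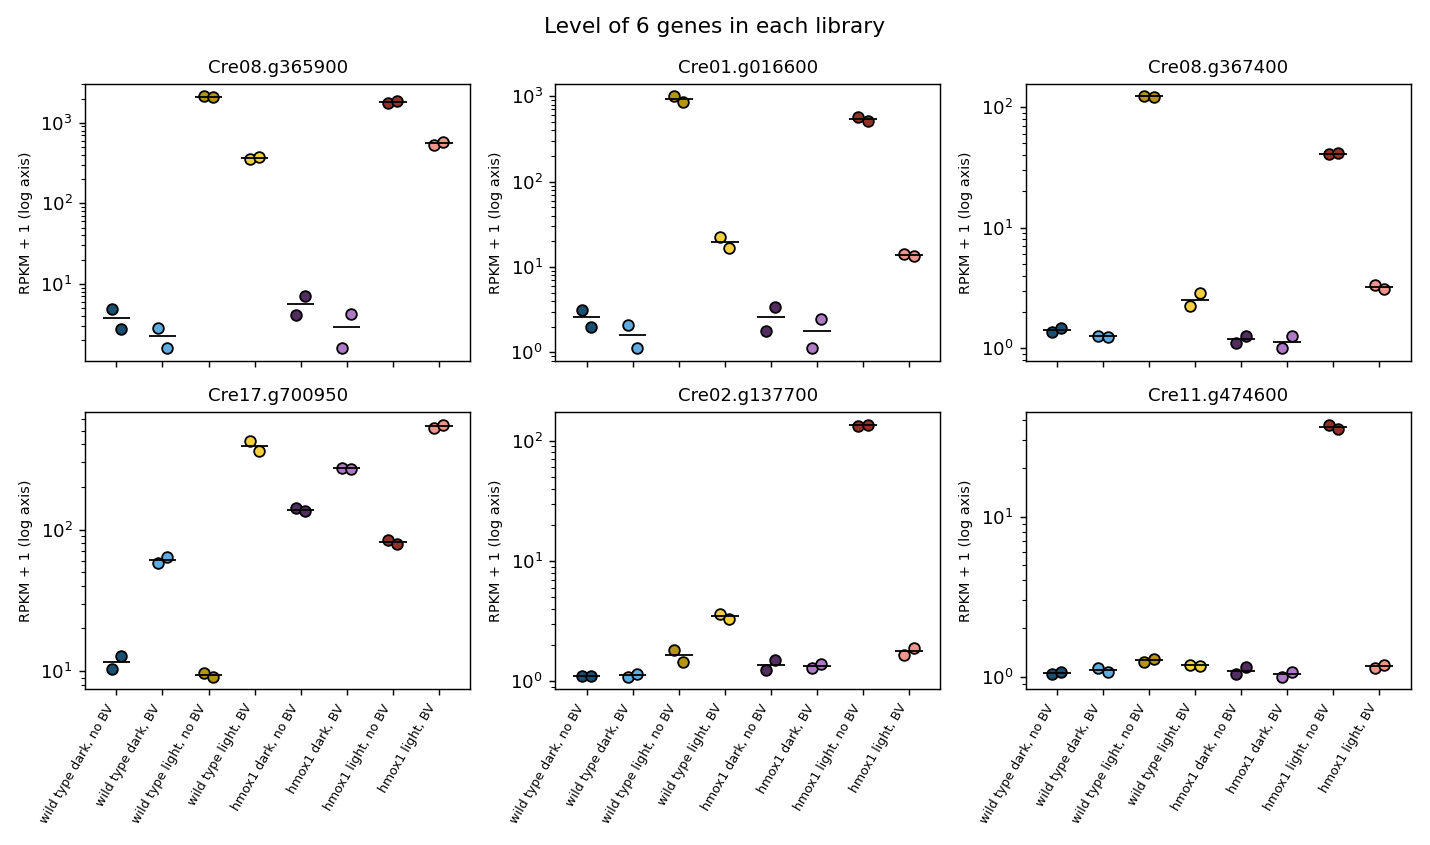
Levels of 6 genes in each library as RPKM + 1 on a log axis, with the 8 groups on the x axis, a point per library and a line at the group mean. Cre01.g016600 falls from 924 to 18.6 RPKM with BV in light-treated wild type, and Cre02.g137700 is high (133.5 RPKM) in hmox1 in the light without BV.

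Light changed most genes. In wild type without BV, Cre08.g365900 rose from 2.78 ± 1.495 to 2114 ± 27.3 RPKM (SD, n = 2; log2 difference 9.19 ± 0.49, limma adjusted p = 1.4e-07). Cre07.g320400 rose from 1.99 ± 0.502 to 1575 ± 21.7 RPKM, with a recovered length of 148 nt. Cre16.g661200 fell from 165.4 ± 8.09 to 1.51 ± 1.28 RPKM (log2 difference -6.15 ± 0.40, limma adjusted p = 3.8e-07), and Cre10.g424583 from 233.4 ± 24.1 to 2.73 ± 2.24 RPKM. In hmox1 without BV Cre08.g365900 reached 1810 ± 64.2 RPKM and Cre07.g320400 reached 992 ± 85.6. Cre13.g603550 fell from 93.8 ± 5.20 to 1.43 ± 0.949 RPKM (log2 difference -5.34 ± 0.28, limma adjusted p = 2.6e-08), and Cre16.g661200 fell by 5.28 on the log2 scale. With BV, Cre08.g365900 reached 363 ± 15.9 RPKM in wild type and 558 ± 36.3 in hmox1. Cre07.g320450, of 146 nt, reached 491.7 ± 13.3 and 421 ± 25.5 RPKM. Cre16.g661200 fell by 6.95 and 5.84 on the log2 scale. Cre06.g263200 fell by 5.94 in wild type and Cre11.g474100 by 4.23 in hmox1.

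Limma called 2919 genes higher and 8811 lower after light in wild type without BV, 2971 and 7718 in hmox1 without BV, 3271 and 7757 in wild type with BV, and 2856 and 5720 in hmox1 with BV. The median gene fell by 0.57, 0.35, 0.37 and 0.16 in log2 in that order. The shares of higher genes were 24.9%, 27.8%, 29.7% and 33.3%, against 48.8%, 50.5%, 50.7% and 50.1% with TMM and 45.6%, 44.3%, 48.4% and 46.3% with quantile scaling.

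**Figure D3:**
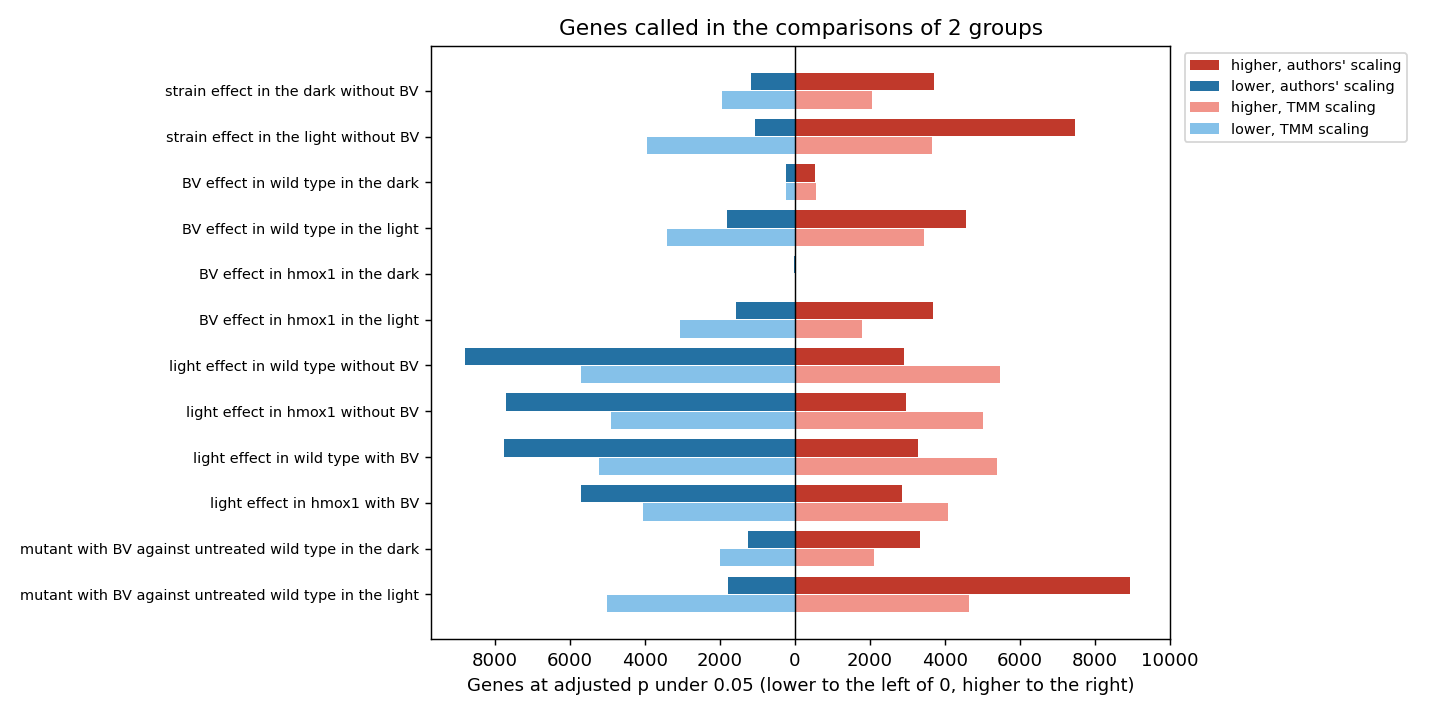
Number of genes called at adjusted p under 0.05 in the 12 comparisons of 2 groups, with higher genes to the right of 0 and lower genes to the left, dark bars for the authors' scaling and pale bars for TMM scaling. In wild type without BV light raised 2919 and lowered 8811 genes on the authors' scaling, and 5457 and 5715 with TMM.

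The size of the light response depended on the strain and on BV. Averaged over the 4 conditions, 1030 genes rose and 2229 fell 2-fold or more in the light. The 1030 risers had median log2 light effects of 1.95 in wild type without BV, 1.61 in wild type with BV, 1.62 in hmox1 without BV and 1.18 in hmox1 with BV. For the 2229 fallers the medians were -1.74, -1.45, -1.24 and -0.88. The order was the same in each library of the light-treated groups for fallers. For risers, replicate 2 of wild type with BV (1.70) lay above both libraries of hmox1 without BV (1.61 and 1.64), and replicate 1 (1.49) below both. With TMM scaling the sets held 1739 risers and 1135 fallers, and with quantile scaling 1250 and 1116, and both medians stayed closer to 0 with BV in each strain.

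**Figure D4:**
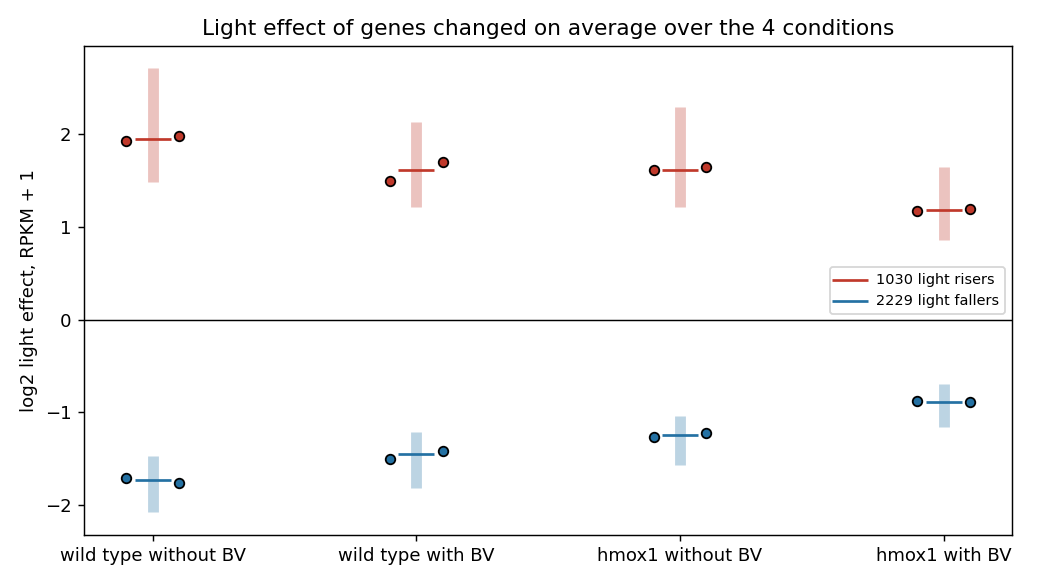
Median log2 light effect on RPKM + 1 of 1030 light risers and 2229 light fallers in the 4 conditions on the x axis. Bars at the centre of each condition span the quartiles over genes, and short lines mark the medians, from 1.95 to 1.18 for the risers. Points mark the median of each light library against the mean of its dark group.

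By the test of the difference, the light effect differed between strains without BV in 4330 genes, 3314 more positive and 1016 more negative in hmox1. Of the risers, 489 rose less in hmox1 and 58 more, and of the fallers 1179 fell less and 26 more, and the direction of both was the same with TMM (1267 and 53, 558 and 18) and quantile scaling (544 and 64, 413 and 23). Cre02.g137700 and Cre11.g474600 had the most positive differences among such genes, 6.05 ± 0.17 and 4.80 ± 0.12 (SE, limma adjusted p = 1.2e-12 and 1.8e-13). Cre13.g569400 rose from 0.852 ± 0.676 to 66.2 ± 11.8 RPKM in wild type (SD, n = 2). In hmox1 Cre13.g569400 rose from a higher dark level, 3.315 ± 0.188, to 18.2 ± 0.168 RPKM. The difference of log2 effects was -3.06 ± 0.27 (SE, limma adjusted p = 6.9e-06). Cre07.g339300 fell from 16.7 ± 0.635 to 1.53 ± 0.184 RPKM in hmox1 while wild type stayed near its read floor, and its call was lost with voom. The share of more positive genes was 76.5%, against 45.5% with TMM and 50.6% with quantile scaling, and the count was 2876 without replicate 2 of light-treated hmox1.

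BV changed the light effect in 4394 genes of wild type, 3113 more positive and 1281 more negative, and in 3171 genes of hmox1, 2217 and 954. Among the 1030 risers, 438 rose less with BV in wild type and 460 in hmox1, against 78 and 16 that rose more. Among the 2229 fallers, 604 and 798 fell less, against 98 and 15 that fell more. The majority had the same direction with TMM and quantile scaling, with 227 against 97 and 213 against 126 for the fallers in wild type. Cre08.g367400 and Cre08.g367500 lost most of their light response in wild type, with differences of -5.42 ± 0.18 and -4.91 ± 0.17 (SE, limma adjusted p = 1.3e-11 for each). Cre10.g443050 fell from 102.4 ± 26.2 to 5.06 ± 0.797 RPKM without BV but stood at 124 ± 28.6 and 122.7 ± 9.24 RPKM with BV (difference 4.08 ± 0.26, limma adjusted p = 6.8e-07). In hmox1 Cre02.g137700 and Cre11.g474600 had differences of -6.22 ± 0.17 and -4.89 ± 0.12. Cre07.g346950 had positive differences in both strains, 3.52 ± 0.12 in wild type and 2.97 ± 0.12 in hmox1, and Cre02.g118550 one of 3.05 ± 0.62 in hmox1. The shares of more positive genes were 70.8% in wild type (48.1% with TMM, 54.8% with quantile scaling) and 69.9% in hmox1 (33.2% and 48.5%). The wild-type count was 5277 and 4128 without replicate 1 and 2 of the light libraries with BV, which differed most from each other, and the hmox1 count was 1969 without replicate 1 of the untreated light libraries.

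The mutant supplied with BV was compared with untreated wild type, which addresses how near BV brought the mutant to wild type. In the dark 4591 genes differed, 3343 higher and 1248 lower in the mutant. Cre17.g700950 was at 268.9 ± 5.17 against 10.6 ± 1.62 RPKM (SD, n = 2; log2 difference 4.55 ± 0.09, limma adjusted p = 1.5e-14), and Cre07.g339300 at 18.5 ± 0.435 against 0.0556 ± 0.0380. Cre03.g204200 had 2 reads against 524, a rate 243.8-fold lower with a 95% Poisson interval of 67.2 to 2018, and Cre37.g784950 had 0 against 96, at least 29.8-fold lower with that floor (lower 95% Poisson limit 23.75). Of the 4893 genes that differed between untreated strains in the dark, 3896 (79.6%) still differed in the same direction with BV, 995 no longer did and 2 differed in the opposite direction. Both of these comparisons use the untreated wild-type libraries, so agreement is favoured by the shared controls. BV in hmox1 changed 25 of them towards wild type and 11 away from it, against 7.1 and 8.7 for independent lists. The strain effect and the BV effect in hmox1 share the untreated hmox1 libraries, so independent lists are not the only reference. Across genes, the dark strain effect and the dark BV effect in hmox1 had a covariance of -0.0088, and unchanged groups simulated against the same libraries gave -0.0092.

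In the light 10718 genes differed between the mutant with BV and untreated wild type, 8929 higher and 1789 lower. Cre08.g372200 was at 646.9 ± 50.8 against 9.26 ± 1.07 RPKM (SD, n = 2; log2 difference 5.98 ± 0.13, limma adjusted p = 1.7e-13), and Cre17.g700950 at 537.6 ± 18.6 against 8.43 ± 0.417. Cre01.g016600 and Cre08.g367400 were lower, by -6.07 ± 0.47 and -5.24 ± 0.13 in log2 (SE, limma adjusted p = 3.3e-06 and 2.1e-14). Of the 8557 genes that differed between untreated strains in the light, 7768 (90.8%) still differed in the same direction with BV, 664 no longer did and 125 differed in the opposite direction, again against the same untreated wild-type libraries. The BV effects of both strains in the light correlated with r = 0.71, so changes common to both strains enter the counts that follow. BV in hmox1 changed 620 of these 8557 genes towards untreated wild type and 2886 away from it, against 1120.2 and 2087.8 for independent lists. With TMM the numbers were 604 and 2627 against 1332.2 and 1358.6, and with quantile scaling 613 and 1656 against 880.4 and 879.9. The light strain effect and the light BV effect in hmox1 had a covariance of 0.0323, against -0.0092 for simulated unchanged groups. The shares of higher genes were 72.8% in the dark (51.3% with TMM, 50.5% with quantile scaling) and 83.3% in the light (48.1% and 52.0%).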

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

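The tests of scaling, depth, mixing and left-out libraries were chosen after the results they weigh were seen, while the tests of split hmox1 libraries, of other groupings and of the choice of light genes were set before their results were seen. In 5 comparisons of effects, the test of the difference itself called genes. The light effect differed between strains without BV in 4330 genes and between cells with and without BV in 4394 genes of wild type and 3171 of hmox1. The BV effect differed between strains in 131 genes in the dark and 1196 in the light.

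The median light response of both risers and fallers was smaller with BV, but part of the change was a shift of all genes. Measured from the median of all genes, the riser median went from 2.51 to 1.98 with BV in wild type and from 1.96 to 1.34 in hmox1. The faller median so measured went from -1.17 to -1.08 and from -0.89 to -0.72. The difference between riser and faller medians, given next, therefore rests more on the risers. In wild type the riser median lay above the faller median by 3.68 in log2 without BV and 3.06 with BV, in hmox1 by 2.86 and 2.06. A scaling factor shifts both medians in the same direction, and the loss in wild type was still 0.42 under quantile scaling, the smaller of both rescalings, and 0.59 with libraries thinned to 1 depth. The choice of genes by a mean that untreated wild type influenced most does not account for it either, as with genes chosen on hmox1 libraries alone, without or with BV, the loss in wild type was 0.70 and 0.60. RNA of dark cells mixed into the light libraries would bring each riser to the same mixture of its dark and light levels. The variance around the best mixture in wild type was 30.6 times the mean squared standard error over 1030 risers. This argues against mixing as the whole explanation only if the spread between libraries covers that between cultures, which the labels do not say. Mixing as part of the cause is not excluded. A weaker response of the cells to light, and less light reaching cells in medium with a pigment, both remain open and were not tested.

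BV changed more genes in the dark in wild type (764) than in hmox1 (45), and 122 of the 131 genes with a tested difference changed more negatively in hmox1. Unequal depth does not account for it: with libraries thinned to the shallowest depth the wild-type count was 18.8 times the hmox1 count. Nor does a single library, since the lowest wild-type count with 1 library left out (248, without BV replicate 1) was 5.5 times the hmox1 count from all libraries (45), and the highest hmox1 count with 1 dark hmox1 library left out was 29. A biological difference of hmox1, such as its uptake or use of BV, may underlie it and was not tested.

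Some genes that were higher in light-treated hmox1 were lowered there by BV. Of 692 genes at least 2-fold higher in hmox1 than in wild type in the light, 43 were lowered at least 2-fold by BV in hmox1, against 11.7 for independent lists. Of the 43, 35 were not lowered 2-fold by BV in wild type. The choice of genes partly fixes this count, since a gene under 1 RPKM cannot fall 2-fold on the log2(RPKM + 1) scale. Cre02.g137700 and Cre11.g474600, for example, were at 0.641 and 0.265 RPKM in light-treated wild type without BV. The count thus does not show that the lowering is particular to hmox1. In the other direction, 1 of the 61 genes at least 2-fold lower in hmox1 was raised by BV, against 0.9 for independent lists. Both effects use the same hmox1 libraries, whose chance values could create such an overlap. With replicate 1 serving for the strain effect and replicate 2 for the BV effect the count was 46, and with the roles exchanged it was 43, against 12.3 and 12.2 for independent lists, which argues against chance values of single libraries. If both libraries came from 1 culture, chance values of that culture remain open. For these 43 genes, a lowering effect of BV on genes raised in hmox1 in the light is a candidate explanation. It was found and tested on the same data. Of all genes that differed between the strains in the light, BV in hmox1 moved more away from untreated wild type (2886) than towards it (620).

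The contrast of light with dark rested on 8 against 8 libraries, and 3254 genes changed at least 2-fold in it. Among 100 splits of the 16 libraries only 1, the real one, gave as many genes, and the highest of the others gave 1754. Among the 35 divisions that keep both libraries of a group together, again only 1, the real one, gave as many, with 1248 as the highest of the others. Light was an applied treatment that already parted the libraries on the first component, so these ranks restate that separation. The 100 splits also parted libraries of the same group, which are not interchangeable. With 35 divisions no share below 1 of 35 was possible. The counts thus show that light gave more genes than any other division examined, and do not measure chance.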

How the results depend on the processing

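The settings voom, thinning, a 200-nt length minimum and leaving out both libraries of light-treated wild type with BV were chosen after seeing the data. Counts, medians of the light sets and correlations, 3135 values in all, were recomputed over 13 settings and 16 left-out libraries. Of these, 2617 stayed near the reported value, 518 moved further and 0 reversed. Near meant within 1.5 times for counts and the same sign for correlations. For medians it meant at most 1.5 times the reported value and no nearer to 0 than to that value. Counts cannot reverse, and the light sets were chosen again by sign in each setting. Only the correlations could therefore readily have reversed. The median of all genes and the majority direction of calls are not among these values: with TMM the median changed from 0.12 to -0.0040 for the strain in the dark, from 0.13 to -0.0233 for BV in light-treated hmox1 and from -0.37 to 0.0073 for light in wild type with BV, by the centring. Of 68 pairs of a printed gene and a comparison, 58 passed the threshold in each setting and 10 did not in 1 or more, and none reversed. A gene left out for too few reads, Cre10.g429950, did change direction with thinned libraries in the BV comparison in dark hmox1, and is not among these. Fewer genes tested or a fold minimum lower a count by construction. Leaving out a library also tends to lower a count, as its group then holds 1 library. For the other changes the cause was not tested. The tests on gene lists were not run, as no list could be filled. Shared calls at adjusted p under 0.01 stand among the recomputed counts. Where a library was left out, its partner was assumed to vary like the other groups.

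Same-numbered libraries shared at most a weak deviation. Over 28 pairs of groups their deviations correlated with a median r of 0.07 (range -0.15 to 0.27), and above 0.1 in 10 pairs. Whether the number marks a pairing, such as dark and light samples of the same culture, cannot be told from these values. With the number as a block the counts were 5258 and 8851 for the strain in the dark and light, 974 and 6658 for BV in wild type, and 52 and 5612 for BV in hmox1, and no total moved by more than 1.5 times. By direction, genes lowered by BV in dark wild type went from 241 to 373, and genes with a more positive BV change in dark hmox1 from 9 to 15.

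With a minimum of 10 RPKM the counts were, for the strain, 2866 in the dark and 3659 in the light; for BV, 3204 in wild type in the light, 28 in hmox1 in the dark and 2506 in the light; for light, 4924 and 4530 without BV and 4729 and 3835 with BV in wild type and hmox1; for the mutant with BV against untreated wild type, 2622 and 4415; and for the differences, 2156 (light by strain), 50 (BV by strain in the dark), 2445 and 1627 (light by BV in wild type and hmox1). With a 2-fold minimum they were, for the strain, 482 and 753; for BV, 80 and 645 in wild type and 5 and 451 in hmox1; for light, 5370 and 3212 without BV and 3988 and 1526 with BV; for the mutant with BV, 495 and 2322; and for the differences, 463, 48 and 175 (BV by strain in the dark and light), 735 and 449.

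BV in dark wild type gave 1187 genes with only the groups compared and 1357 without both libraries of light-treated wild type with BV, whose spread then no longer entered the pooled estimate. BV in dark hmox1 gave 29 thinned, 82 with only the groups compared and 24 with a pseudocount of 0.1. The BV difference between strains gave 71 thinned and 56 with that pseudocount in the dark, and 791 thinned and 716 with only the groups compared in the light.

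With 1 library left out, counts ranged from 248 to 467 for BV in dark wild type, 21 to 29 for BV in dark hmox1, 3194 to 3811 for BV in light-treated hmox1, 71 to 108 and 601 to 2111 for the BV difference between strains in the dark and light, 2876 to 3613 for the light difference between strains, and 1969 to 2427 for the light by BV difference in hmox1. Voom on the recovered reads called 4885 genes for the strain in the dark, 959 for BV in dark wild type and 11620 for light in wild type without BV. Depth limits the low genes: at 10213599 reads, 3 reads of a 2-kb gene make 0.147 RPKM.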

Other observations

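The BV effect in the light ran opposite to the light response of the other strain, in comparisons that share no library. Over 13972 genes, the BV effect in light-treated wild type correlated with the light effect in untreated hmox1 with r = -0.53, and the BV effect in light-treated hmox1 with the light effect in untreated wild type with r = -0.63. Of the 1814 genes that BV lowered in light-treated wild type, 1316 rose with light in hmox1, against 385.7 for independent lists, and of the 1563 that BV lowered in hmox1, 1261 rose with light in wild type, against 326.5. Genes are not independent replicates, and r describes these libraries only. The values are on the authors' scaling, on which the median gene rose by 0.13 with BV in each strain. It fell with light by 0.35 in hmox1 and 0.57 in wild type. Such opposite shifts can by themselves add to a negative r and to these overlaps. The sign of r did not reverse with TMM or quantile scaling. The calls also share the pooled spread of each gene. In the dark the BV effects of both strains correlated with r = 0.32, and within wild type the dark and light BV effects with r = 0.16.

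A few genes had nearly all of their reads in 1 strain. Chosen after their values were seen, 5 genes had at least 100 reads over the 8 hmox1 libraries and at most 3 over the 8 wild-type libraries: Cre03.g205500 (1443 against 3), Cre01.g042700 (316 against 1), Cre12.g483720 (247 against 1), Cre08.g360444 (117 against 3) and Cre13.g598650 (104 against 0). In the other direction 1 gene met the same rule, Cre15.g642800, with a recovered length of 58 nt and 3 reads over the 8 hmox1 libraries. The limit of 3 reads narrowly left out Cre03.g204200, of 722 nt. Without BV that gene had 524 reads in wild type against 0 in hmox1 in the dark, and 762 against 2 in the light. With BV its hmox1 libraries held 1 read each in the dark and 0 in the light.

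The test of neighbouring genes was chosen after its result was seen. A hypothesis was that neighbours share part of their response even where they do not overlap. Over 927 adjacent pairs at least 1000 nt apart in the RefSeq assembly Chlamydomonas_reinhardtii_v5.5, the mean light effects correlated with r = 0.23, and the highest of 1000 shuffles of the gene order gave 0.11, which is consistent with the hypothesis. The BV effect in light-treated wild type gave 0.20 against a highest shuffle of 0.10. Close copies that lie next to each other and share reads could also give such correlations, since a gap of 1000 nt does not exclude them. This was not tested. The strain effect in the dark gave 0.03 against 0.11 and the BV effect in light-treated hmox1 0.12 against 0.16, so neither stood outside the shuffles.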
